A study of Mus musculus with 5 samples.

How the data were processed

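The series holds single-cell transcript counts from 5 plates of mouse colorectal cancer cells recovered from the liver. Per the labels' protocols, the cells were an organoid line, a culture of tumour cells grown in a gel, with conditional loss of Apc, an inducible mutant Kras allele, Tp53 knocked out, a red fluorescent protein and a DTR-eGFP reporter (diphtheria toxin receptor joined to green fluorescent protein) at the Lgr5 locus. Per the labels, cells sorted as Lgr5 negative or Lgr5 positive were injected into the portal vein of immunodeficient NSG mice, livers were digested with collagenase on days 1, 7, 13 and 27, and live single red fluorescent cells were sorted into 384-well plates. The labels place cells from injected Lgr5-negative cells in wells 1 to 192 of each plate and those from injected Lgr5-positive cells in wells 193 to 384. About 400000, 200000, 200000 and 50000 cells were injected for days 1, 7, 13 and 27.

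Per the labels' protocols, libraries were made by SORT-seq, a plate version of CEL-seq2 in which each well has a barcode and each captured 3′ end a random molecular barcode. The submitters' processing notes name BWA and mm10, with no version of BWA. The annotation, the strand used in counting and any filter on wells or genes are not given in the sources used here. The deposited values are expected counts of transcripts per gene and well: whole molecule numbers corrected for chance reuse of the 4096 possible molecular barcodes, as read from the values themselves, which invert to whole numbers under that correction. They were summed over wells and rounded to whole numbers before any count test. The files listed 14849 to 15833 genes each, 18269 nuclear genes together, beside 87 spike-in entries and the mitochondrial genes. Spike-ins and mitochondrial genes were kept out of library sizes and tests. Names of the processed files placed days 1 and 7 on 1 sequencing run and days 13 and 27 on another, so run, day and injected number cannot be told apart for some comparisons.

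Wells with at least 1000 transcripts of nuclear genes and at most 50% mitochondrial transcripts were kept, 1356 in all. Cells were scaled to 10000 transcripts, log-transformed and clustered on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 0.8 and seed 1, in scanpy 1.11.5 with igraph 0.11.9 under Python 3.11.15. Of the 13 clusters, 1 was led by class II antigen presentation genes and was clustered again into 5 parts, a step chosen after its leading genes were seen. A cluster was called hepatocyte-like, myeloid-like or endothelial-like when at least 3 markers of that type stood among its 50 leading genes. The other cells, called tumour cells here, numbered 1112. No doublet caller was run, because single cells were sorted into wells, so doublets and free RNA are not excluded.

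Cells are not replicates. The tumour cells of each injected fraction on each plate were summed to a half-plate profile, 10 in all, with 1100640 to 2956694 transcripts. Genes were filtered with edgeR's filterByExpr, which left 10367, and scaled by TMM. In edgeR 4.0.16 under R 4.3.3 the robust quasi-likelihood test was fitted to the 10 half-plates with plate and injected fraction as additive terms. The fit had 4 residual degrees of freedom, a median of 21.8 prior degrees of freedom and a common biological coefficient of variation of 0.121. Day contrasts were called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold of at least 1 in size, day 27 being the mean of its 2 plates. The difference between the 2 day 27 plates, from the same fit, served as a yardstick for plate effects. The effect of the injected fraction and its interaction with log2 day were called at an adjusted p under 0.05. A trend over log2 day was tested on the 5 plate sums (11265 genes), where the scatter between plates enters the error. Standard errors are the size of the log2 fold divided by the square root of the quasi-likelihood F. Values in CPM, counts scaled to a common library total, are given as mean ± SD over half-plates, n = 2 for days 1, 7 and 13 and n = 4 for day 27. The labels do not say how many animals stand behind a plate, or whether plates came from separate animals or injections. Both fractions carried the same red fluorescent protein, so recovered cells could be told apart only if the fractions were injected apart. A difference between fractions is then also one between injections. Every p-value covers only the spread between half-plates or plates, which may be technical. 3 counts in a half-plate correspond to between 1.01 and 2.73 CPM.

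Gene lists were tested with limma 3.58.1: camera with a preset correlation of 0.01 on log-CPM with a prior count of 2, adjusted over the 27 lists with enough measured members, and as alternatives camera with an estimated correlation and fry. Beside each test stands the number of members called over all genes and with p-values adjusted over the list alone. The enteroendocrine, erythroid and lymphoid lists had too few measured members and the mitochondrial list is outside the library sizes, so these were not tested. Shares of cells with a transcript of a gene were taken after each cell was thinned to 1000 transcripts, with exact (Clopper-Pearson) 95% intervals that cover counting error only. Between injected fractions, shares were compared by a two-sided exact sign-flip permutation over the 5 plates, for which the smallest possible p is 0.0625. Gene positions are from the GRCm38 (mm10) annotation given with the data.

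The genes named were chosen by rule. For each day contrast and the fraction effect these were the 8 called genes with the largest fold in each direction, with a mean of at least 50 CPM and the same direction in both fractions, or for the fraction effect in at least 4 of the 5 plates. In each list up to 4 called members with the smallest adjusted p were named, or the member with the highest CPM if none was called. A set of 20 key genes was always to be named. Trend and interaction genes were the 8 with the smallest p in their tables, with further interaction genes given as members of a list, and Amotl2 was named for the fraction effect after its values were seen. The groups, tests, lists, markers, the naming rule and most alternatives were fixed before the data were examined. Alternatives were DESeq2 size factors, no gene filter, DESeq2 1.42.0, at least 500 or 2000 transcripts per cell, other cell types kept, no mitochondrial limit, half-plates thinned to equal depth, limma on mean log values per cell (pseudocount 1), leaving out each plate, day 27 plates summed, adjusted p alone, no plate block, day untransformed, and limma-voom with plate as a random block. Added after seeing the data were leaving out Rn45s (a ribosomal RNA precursor), whole molecule numbers, cells under 0.3% of other-type markers, leaving out the cluster led by Kcnq1ot1, keeping the class II cluster whole, and the share of cells with the reporter.

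The tests were tried on simulated counts with the real means and library sizes and 200 changed genes. The spread came from the fit with plate terms, so the simulated plates carried no plate-to-plate noise. The recovery and false calls below do not cover such noise, which the day contrasts and the trend meet in the real data. For day 7 against day 1, 34.0% of 2-fold and 83.7% of 4-fold changes were called by the rule used, with 5 false calls among 10148 genes. A 2-fold change sits on the fold limit, and at the adjusted p alone 52.0% were recovered with 9 false calls. For day 27 against day 1, 36.5% and 94.8% were called with 1 false call among 10126 genes. The fraction effect gave 90.0% and 98.0% with 12 among 10138 genes, and the trend 65.7% and 93.0% with 13 among 10365 genes. For the interaction only 4.12% and 52.5% were recovered, with 5 false calls among 10134 genes. In a simulation of the list test, 1 list of 20 genes was moved 1.5-fold. It was found at a camera adjusted p of 5.89e-12, or 0.0355 with an estimated correlation, and no other list was called. Genes were drawn independently of each other, and the other lists were random genes. The absence of false lists therefore does not carry over to the real lists, whose genes may vary together.

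Chga was not analysed here, and Olfm4, with 1 count in all, was too low to test. Genes with near-identical relatives, among them Hspa1a and Hspa1b, Ifi27l2a and Ifi27l2b, Ces2a, Clca4, Ly6a, the ribosomal proteins and the multicopy Rn45s, are uncertain because it is not known how reads shared between copies were counted. So are genes that overlap another gene, such as Lgr5 with A930009A15Rik, Cryab with Hspb2 and H19 with Mir675.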

Results

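The series followed mouse colorectal cancer cells through 27 days in the liver, after organoid cells sorted by their Lgr5 state had been injected into the portal vein. Lgr5, a receptor that strengthens Wnt signals, marks stem cells of the intestine, and the design asks how tumour cells change while they colonise the liver and whether this depends on the Lgr5 state of the cells injected. There was 1 plate of 384 single-cell wells for each of days 1, 7 and 13 and 2 plates for day 27. On each plate 192 wells held cells from injected Lgr5-negative cells and 192 wells cells from injected Lgr5-positive cells. The deposited transcript total was 4880880 for day 1, 4411080 for day 7, 5537950 for day 13, and 5281400 and 5581500 for the 2 day 27 plates. Tumour cells held a median of 12543, 10988, 10667, 10468 and 11978 nuclear transcripts on the 5 plates in that order. The number of cells injected was largest for day 1, the same for days 7 and 13, and smallest for day 27. Days 1 and 7 were sequenced on another run than days 13 and 27, so a difference between day 7 and day 13 is also one between runs. The contrast of day 27 with day 1 spans both the run and the injected number. Because days 1, 7 and 13 had 1 plate each, the p-values of day contrasts cover the spread between the half-plates of a plate and not that between plates.

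Wells with liver cell profiles were common on the plates of the first week and rare afterwards. Of the wells past the filters, wells of other types made up 41.6% at day 1, 35.9% at day 7, 5.91% at day 13, and 2.20% and 1.09% at day 27. Myeloid-like wells numbered 74 at day 1 and 79 at day 7, against 4 at day 13 and 2 and 1 at day 27. Of these, 62 at day 1 and 67 at day 7 were in a cluster led by the Kupffer cell genes Clec4f, C1qb and C1qc, and 12 on each of the plates were in a sub-cluster led by the class II genes H2-Aa, H2-Ab1 and Cd74. Endothelial-like wells, led by Igfbp7, Sparc, Clec4g, the mesenchymal marker Dcn and Dnase1l3, numbered 23, 13, 7, 3 and 2. Hepatocyte-like wells, led by Alb, Apoa2 and Ttr, numbered 17, 15, 3, 1 and 0. Epithelial markers took a median of 0.603% of transcripts in hepatocyte-like wells and 0.676% in endothelial-like wells, close to the 0.855% of tumour wells, and 0.109% in myeloid-like wells. Epcam was found in 91.7% of hepatocyte-like, 83.3% of endothelial-like and 45.0% of myeloid-like wells, so doublets with tumour cells or free RNA in these wells are not excluded. Tumour wells also held liver transcripts, most at the early days. Hepatocyte markers took 0.120% of their transcripts at day 1, 0.0930% at day 7, 0.0309% at day 13, and 0.0299% and 0.0231% at day 27. The mitochondrial share of tumour cells was 16.9% at day 1, 12.3% at day 7, 10.5% at day 13, and 10.5% and 9.85% at day 27.

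**Figure D1:**
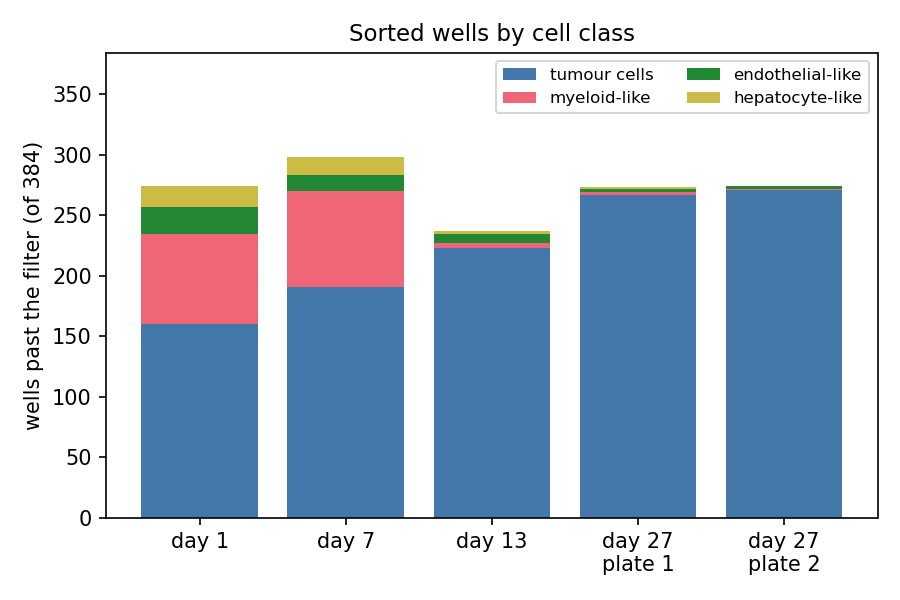
Bars show the number of wells past the filters on each of the 5 plates, of 384 wells per plate, stacked by class (tumour, myeloid-like, endothelial-like, hepatocyte-like). Tumour wells numbered 160 at day 1 and 271 on the second day 27 plate, and myeloid-like wells numbered 79 at day 7 and 4 at day 13.

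Trp53, the gene knocked out in this line (chromosome 11, 69580359 to 69591873), was still read in every half-plate. Its level lay between 98.5 and 147 CPM over the 10 half-plates. The 3′ tag that is counted may lie outside the deleted part, so these values check nothing about the knockout. No difference in Trp53 was found between day 27 and day 1 (log2 fold 0.09, edgeR adjusted p = 0.688).

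Between day 1 and day 7, some genes of secretory goblet cells and some Wnt targets rose, while some targets of YAP, a regulator of tissue repair, and some inflammatory genes fell. Muc2, the main mucin of the gut (chromosome 7, 141690340 to 141754693), went from 24.3 ± 13.2 to 539 ± 120 CPM (SD, n = 2 half-plates each), a log2 fold of 4.48 ± 0.46 (SE; edgeR adjusted p = 0.0110). Agr2, a protein folding enzyme needed for mucin (chromosome 12, 35992907 to 36004087), rose from 51.1 ± 32.8 to 483 ± 3.14 CPM, by 3.28 on the log2 scale (edgeR adjusted p = 0.0149). Of the 15 measured goblet genes 6 rose, none fell and 9 did not pass, among them Fcgbp at 2.73 and the tryptase Tpsg1 at 2.78 on the log2 scale (adjusted over the list alone, 9 rose). The camera test gave a median of 1.96 and an adjusted p of 5.44e-09, with an adjusted p = 0.187 with an estimated correlation. Of 16 Wnt targets 4 rose and none fell, namely the Wnt inhibitors Wif1 (3.51) and Notum (1.38) and the transcription factors Prox1 (1.14) and Sox4 (1.25), and 5 rose adjusted over the list alone (camera adjusted p = 3.33e-06, but an adjusted p = 0.148 with an estimated correlation).

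A tumour cluster led by Cryab and Ly6a, with Ankrd1 among its top genes, held 59 cells at day 1 and 6 at day 7. The changes that follow may include this change in the number of such cells. YAP targets were mixed from day 1 to day 7. Of 18 measured, 5 fell and 1 rose, including Amotl2 (−2.04), a junction protein that restrains YAP, Ctgf (−1.99), Myof (−1.61), Lats2 (−1.36) and Ajuba (−1.15), and 6 fell and 1 rose adjusted over the list alone. The camera adjusted p was 0.000862, and the adjusted p = 0.187 with an estimated correlation. Of 15 NF-kB and inflammatory genes 4 fell and none rose, namely Nfkb2 (−1.27), Tnfaip3 (−2.99), Birc3 (−1.81) and the iron carrier Lcn2 (−2.86), and 7 fell adjusted over the list alone (median −1.25, camera adjusted p = 1.55e-07, but an adjusted p = 0.187 with an estimated correlation). Of 19 fetal or regenerative genes, which the gut turns on during repair, 2 fell, Msln (−1.49) and Plaur (−1.38), and 3 fell adjusted over the list alone (camera adjusted p = 0.00282, but an adjusted p = 0.427 with an estimated correlation). The best known of these, Ly6a (chromosome 15, 74994877 to 74998031), stood at a mean of 1519 CPM at day 1 and 536 ± 75.2 at day 7, a log2 fold of −1.45 that did not pass (edgeR adjusted p = 0.333). Of 14 integrin and basement membrane genes 3 fell, Itgb6 (−2.03), Lama5 (−1.02) and Lamb3 (−1.03), and 4 adjusted over the list alone (camera adjusted p = 0.0136, but an adjusted p = 0.442 with an estimated correlation).

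The other genes with the largest rises from day 1 to day 7 were Hpgds (3.23), a prostaglandin D synthase of tuft cells (chromosome 6, 65117293 to 65144908), the gap junction gene Gjb1 (2.21), Mir5109 (1.87), Rn45s (1.61), Dach1 (1.58) and Glg1 (1.52). Rn45s, the ribosomal RNA precursor, took 1.81% of tumour transcripts at day 1 and 5.50% at day 7. Besides the YAP targets and Msln, the largest falls were those of the actin-binding genes Gsn (−1.78) and Tmsb4x (−1.50), Tm4sf1 (−1.52), Tsc22d1 (−1.43) and S100a1 (−1.39). In all, 133 genes rose and 128 fell of 10367 tested, against 21 and 28 between the 2 day 27 plates. With other cell types kept, Muc2, Gjb1, Tmsb4x and Tm4sf1 were no longer called. Without the day 13 plate neither Ctgf nor Tm4sf1 was called, and without the second day 27 plate Ctgf was not.

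Between day 7 and day 13 Muc2 and several other goblet genes fell back and the regeneration gene Clu rose. Muc2 returned to 20.7 ± 6.02 CPM (SD, n = 2), a log2 fold of −4.62 ± 0.45 (SE; edgeR adjusted p = 0.00789). Of the 15 goblet genes 7 fell and none rose, including Fcgbp (−4.50) and Atoh1 (−3.81), the transcription factor that starts the secretory fate, and 8 fell adjusted over the list alone (median −3.08, camera adjusted p = 9.81e-11, but an adjusted p = 0.248 with an estimated correlation). A cluster of tumour cells led by Ang4, Tff3, Muc2 and Spink4 held 13 cells at day 1, 43 at day 7, 4 at day 13, and 6 and 7 on the day 27 plates, so the goblet changes include a change in the number of such cells. Other tumour cells also sat in different clusters at day 7 and day 13, which were sequenced on different runs. Clusters with Sprr1a, Kcnq1ot1, Tspan32 and Nkd1 among their top genes held 10, 7, 10 and 7 cells at day 7. At day 13 they held 42, 54, 42 and 36. The Kcnq1ot1 and Tspan32 clusters were shallow, with medians of 4256 and 2992 transcripts, against 17006 and 11042 for Sprr1a and Nkd1. Whether low cell quality enters this change was not tested. The 4 tumour parts of the class II cluster held 19, 10, 8 and 29 cells at day 7. At day 13 these parts held 2, 2, 1 and 1. Clu, a secreted chaperone that marks revival stem cells of the injured gut (chromosome 14, 65968483 to 65981547), rose from 223 ± 38.3 to 1513 ± 508 CPM, by 2.77 ± 0.30 on the log2 scale (edgeR adjusted p = 0.00492). With Il33 (1.00) it made up the 2 of 19 fetal or regenerative genes that rose, over all genes and adjusted over the list alone (camera adjusted p = 0.0566). Of 12 absorptive genes 3 fell, Guca2a (−3.23) and Guca2b (−1.96), hormones of mature enterocytes, and the mucin Muc13 (−1.47). The same number fell adjusted over the list alone (camera adjusted p = 0.000728, but an adjusted p = 0.356 with an estimated correlation). Guca2a was also among the top genes of the Muc2 cluster, which went from 43 to 4 cells. Guca2b led a tumour part of the class II cluster that went from 10 to 2 cells. The fall of these hormones may thus include the loss of such cells. Of 19 glycolysis and hypoxia genes 2 rose, Egln3 (1.10) and Car9 (1.78), both targets of the hypoxia factor, and 3 adjusted over the list alone (median 0.63, camera adjusted p = 1.82e-08, but an adjusted p = 0.356 with an estimated correlation).

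Lgr5 (chromosome 10, 115450311 to 115587780) was at 77.2 ± 9.58 CPM at day 7 and 136 ± 25.0 at day 13, a log2 fold of 0.81 ± 0.17 that passed the edgeR test (adjusted p = 0.00507) and stayed under the fold limit. From day 1 to day 7 the log2 fold was −0.05 (edgeR adjusted p = 0.937) and from day 13 to day 27 it was −0.09 (edgeR adjusted p = 0.794). Among the 18 stem cell genes only Ephb3 was called higher at day 13 than at day 7 (1.05), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.860). Liver markers fell at the same step. Of 16 hepatocyte markers 7 fell, such as Ahsg (−2.42), and of 13 myeloid markers 8 fell, such as C1qb (−3.87) and Clec4f (−5.74). Adjusted over the list alone these were 10 and 11, with camera adjusted p of 2.90e-09 and 1.42e-13, and with adjusted p = 0.347 and 0.248 with an estimated correlation.

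Further rises from day 7 to day 13 were those of Lars2 (2.13), Hpgds (1.84), Ace (1.59), Tm4sf20 (1.35), Ddah1 (1.33), Foxq1 (1.29) and Pdlim7 (1.27). Further falls were those of Rpa3 (−2.47), a DNA replication factor, the lipid carrier Apoe (−1.73), the claudin Cldn15 (−1.70), Cdo1 (−1.40) and the succinate dehydrogenase subunit Sdhd (−1.36). Of the 261 genes called 67 rose and the others fell, and with other cell types kept 766 were called. Rn45s took 8.29% of tumour transcripts at day 13, and 4.19% and 3.61% on the day 27 plates.

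From day 13 to day 27 some hypoxia genes and some interferon genes rose, and Mki67 fell. A tumour cluster with Hspa1b, Adm, Pbld1 and Bnip3 among its top genes held 9 cells at day 13. On the day 27 plates it held 48 and 123, so the hypoxia rises may include a change in the number of such cells. Bnip3, a hypoxia-induced mitophagy gene (chromosome 7, 138890836 to 138909519), went from 57.2 ± 14.3 CPM (SD, n = 2) to 222.5 ± 67.3 CPM (SD, n = 4), a log2 fold of 1.94 ± 0.30 (SE; edgeR adjusted p = 0.0257). Of 19 glycolysis and hypoxia genes 6 rose and none fell, over all genes and adjusted over the list alone, with the glucose transporter Slc2a1 (1.32), Car9 (1.33), Vegfa (1.09) and Ndrg1 (1.03) among them (median 0.80, camera adjusted p = 3.52e-13, but an adjusted p = 0.509 with an estimated correlation). The list also differed between the 2 day 27 plates, by a median of 0.56 (camera adjusted p = 1.74e-06, but an adjusted p = 0.516 with an estimated correlation). Of 18 interferon and antigen presentation genes 4 rose, Isg15 (2.90), Psmb8 (1.11), Rsad2 (6.57) and Ifit3 (3.88), and 5 adjusted over the list alone (median 1.15, camera adjusted p = 7.07e-05, but an adjusted p = 0.509 with an estimated correlation). The day 27 level rested mostly on the Lgr5-negative half-plates. Isg15 had 32.6 and 30.7 CPM there, against 3.47 and 5.80 CPM in the Lgr5-positive ones. Ifit3 had 13.3 and 12.1 CPM against 2.32 and 1.29 CPM. From such levels, the log2 fold of 3.88 for Ifit3 rests on a day 13 level near the floor of 3 counts (1.08 and 1.89 CPM). Of 20 G2/M genes none was called, and the list as a whole was lower (median −0.51, camera adjusted p = 7.10e-06, but an adjusted p = 0.509 with an estimated correlation). Mki67, the proliferation antigen, fell by 0.87 on the log2 scale, under the fold limit (edgeR adjusted p = 0.000781).

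Of 19 fetal or regenerative genes 3 rose from day 13 to day 27, Krt4 (1.32), Msln (1.09) and Plaur (1.52), and 4 adjusted over the list alone (camera adjusted p = 0.00173, but an adjusted p = 0.509 with an estimated correlation). Clu stood at 3309 ± 510 CPM at day 27, a log2 fold of 1.11 over day 13 that did not pass (edgeR adjusted p = 0.0811). The YAP target Cyr61 rose by 1.67 (edgeR adjusted p = 0.00915) as the only one of 18 called, while Ctgf was at 1.54 (edgeR adjusted p = 0.0549). Adjusted over the list alone 2 rose (camera adjusted p = 0.000767, but an adjusted p = 0.509 with an estimated correlation). The remaining large rises were Ly6d (1.70), Snhg6 (1.62), Pbld1 (1.58), the metallothionein Mt1 (1.47), Tnfsf9 (1.37) and Rpa3 (1.34). Lars2 (−1.41), Gramd3 (−1.16), Rn45s (−1.15), Apoe (−1.09), the gasdermin Gsdma (−1.07) and the kinesin Kif20b (−1.01) fell. Of the 156 genes called 38 fell and the others rose, and without the second day 27 plate 67 were called, 48 of them shared. Bnip3, Pbld1, Mt1, Lars2, Apoe, Gsdma and Kif20b were then no longer called, and without the first day 27 plate Tnfsf9 was not.

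Over the whole course, day 27 differed from day 1 by higher levels of most glycolysis and hypoxia genes measured, Clu and H19, and by lower levels of some YAP targets, some inflammatory genes and most hepatocyte and myeloid markers measured. H19, an imprinted RNA of fetal growth (chromosome 7, 142575529 to 142578143), had 13.6 CPM in the Lgr5-negative half-plate and 0 in the Lgr5-positive half-plate at day 1, and 1160 ± 64.0 at day 13 and 3002 ± 742 at day 27. Its fitted log2 fold of 8.68 ± 0.82 (SE; edgeR adjusted p = 0.00450) rests on a day 1 level near the floor of 3 counts. Of 19 glycolysis and hypoxia genes 14 rose and none fell, over all genes and adjusted over the list alone, including the glycolytic enzymes Tpi1, Ldha (1.29) and Pkm (1.12) and the oxygen sensor Egln3 (1.24). The median was 1.24 (camera adjusted p = 1.76e-12, but an adjusted p = 0.209 with an estimated correlation). Hypoxia and heat shock genes led the same cluster of tumour cells (Hspa1b, Adm, Bnip3, Hspa1a and Clu among its top genes), with 48 of its 180 cells from the first and 123 from the second day 27 plate and 0 from day 1, while 59 of the 70 cells of a cluster led by Cryab and Ly6a came from day 1. Clu was higher by 4.22 ± 0.30 (edgeR adjusted p = 0.000218), from 177 ± 38.2 CPM at day 1. Of 16 Wnt targets 5 rose, including Notum (2.23), Prox1 (1.49), Wif1 (1.71) and the receptor Ephb2 (1.10), and the same number adjusted over the list alone (camera adjusted p = 3.09e-05, but an adjusted p = 0.176 with an estimated correlation). Lgr5 was higher by 0.67 (edgeR adjusted p = 0.00289), under the fold limit, and Ephb2 was the only one of 18 stem cell genes called.

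Of 18 YAP targets 7 were lower at day 27 than at day 1 and 1 was higher, over all genes and adjusted over the list alone, with Amotl2 (−1.81), Ajuba (−1.19) and Crim1 (−3.93) among the lower, and Axl, for which liver RNA accounted for 151% of the fall (camera adjusted p = 0.0378, but an adjusted p = 0.344 with an estimated correlation). Of 15 NF-kB and inflammatory genes 5 were lower, such as Nfkb2 (−1.48), Relb (−1.16) and the complement gene C3 (−2.16), for which liver RNA in tumour wells, as estimated from the liver-type wells, accounted for 91.9% of the fall, and 7 adjusted over the list alone (camera adjusted p = 2.28e-05, but an adjusted p = 0.209 with an estimated correlation). Of 20 G2/M genes 4 fell, Kif11 (−1.03), Aurkb (−1.05), Nusap1 (−1.06) and Ube2c (−1.10), the same number adjusted over the list alone (camera adjusted p = 1.53e-05, but an adjusted p = 0.481 with an estimated correlation). Hepatocyte markers were lower in 13 of 16, such as Ahsg (−5.67), and myeloid markers in 12 of 13, such as C1qb (−4.29), over all genes and adjusted over the list alone. These 2 lists had camera adjusted p of 5.07e-11 and 1.26e-11, and adjusted p = 0.209 and 0.176 with an estimated correlation.

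Other large rises to day 27 were Hpgds (5.18), the heat shock gene Hspa1a (4.76), the carboxylesterase Ces2a (3.33), Agr2 (3.32), the protease Asprv1 (3.16), Gjb1 (3.11) and Muc2 (2.39). Other large falls were those of the small heat shock gene Cryab (−5.89), Alb (−5.11), Clca4 (−4.06), a gene not found in the annotation used for positions, Apoe (−2.83), the amine oxidase Maoa (−2.48), Tm4sf1 (−2.04), Guca2a (−1.95) and Cdo1 (−1.85). Liver RNA in tumour wells accounted for 110% of the fall of Apoe, and Alb is one of the markers that set its level. Cryab (chromosome 9, 50751325 to 50756636) had 561 CPM in the Lgr5-negative half-plate of day 1 and 61.3 CPM in the other, and at most 8.38 CPM in any half-plate of day 27. Hspa1a had 9.99 and 37.0 CPM on the first day 27 plate and 123 and 347 CPM on the second. In all 459 genes rose and 363 fell. The calls of Hspa1a, Ces2a, Asprv1, Cryab and Alb were lost without the second day 27 plate, and that of Gjb1 with other cell types kept.

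**Figure D2:**
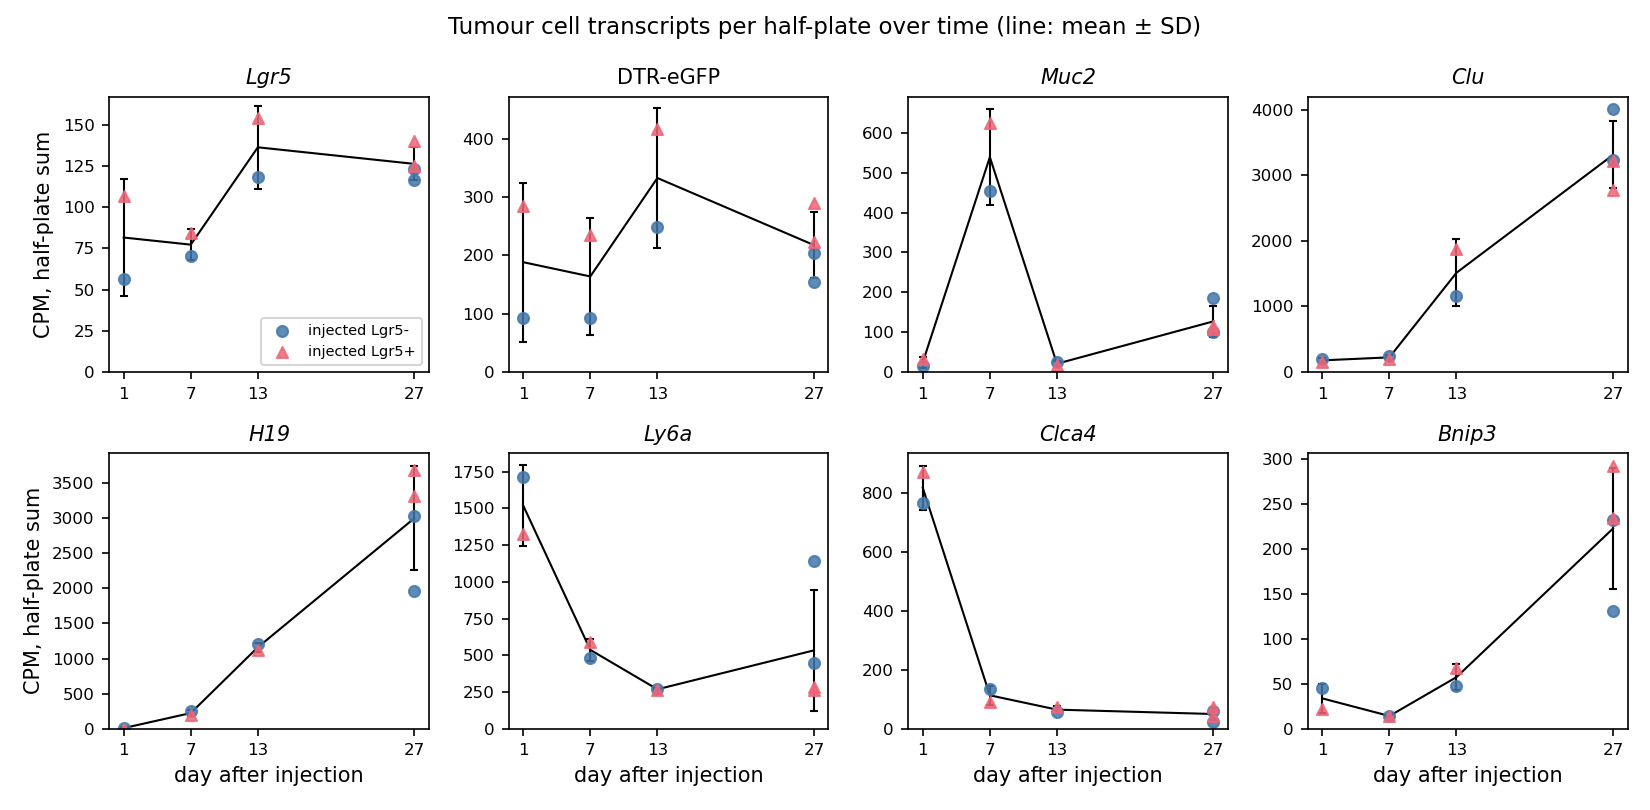
Each panel shows 1 gene, with CPM on the vertical axis against the day of liver perfusion, circles for half-plates from injected Lgr5-negative cells, triangles for Lgr5-positive cells, and a line through the mean ± SD of each day. Muc2 peaked at day 7 with a mean of 539 CPM, Clu reached 3309 CPM and H19 3002 CPM at day 27, and Clca4 stood at 817 CPM at day 1 and 49.4 CPM at day 27.

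Other key genes of the intestinal lineages changed by less than the fold limit or did not pass. Epcam, the pan-epithelial adhesion gene, was higher at day 27 than at day 1 by 0.54 (edgeR adjusted p = 0.00149), and Cdx2, which sets intestinal identity, was at −0.56 from day 13 to day 27 (edgeR adjusted p = 0.0873). The stem cell gene Smoc2 rose by 0.50 to day 7 (edgeR adjusted p = 0.0494) and fell by 0.61 from day 13 to day 27 (edgeR adjusted p = 0.00605). Axin2, a Wnt feedback gene, rose by 0.47 to day 7 (edgeR adjusted p = 0.0400) and fell by 0.60 to day 13 (edgeR adjusted p = 0.00725), and Tacstd2, a fetal gut marker, was lower at day 27 than at day 1 by −0.39 (edgeR adjusted p = 0.0226). Ascl2 and Anxa1 passed in no day contrast. Emp1, a gene of invasive tumour cells, was at −2.09 from day 1 to day 7 (edgeR adjusted p = 0.239), the differentiation keratin Krt20 at 1.71 (edgeR adjusted p = 0.239) and Lyz1, the Paneth cell lysozyme, at 4.07 (edgeR adjusted p = 0.167). At day 7 Lyz1 had 69.1 CPM in the Lgr5-negative half-plate and 554 CPM in the Lgr5-positive half-plate. Ly6a was at −1.68 between day 27 and day 1 (edgeR adjusted p = 0.104), and on the second day 27 plate it had 1141 CPM in the Lgr5-negative half-plate and 284 in the other.

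**Figure D3:**
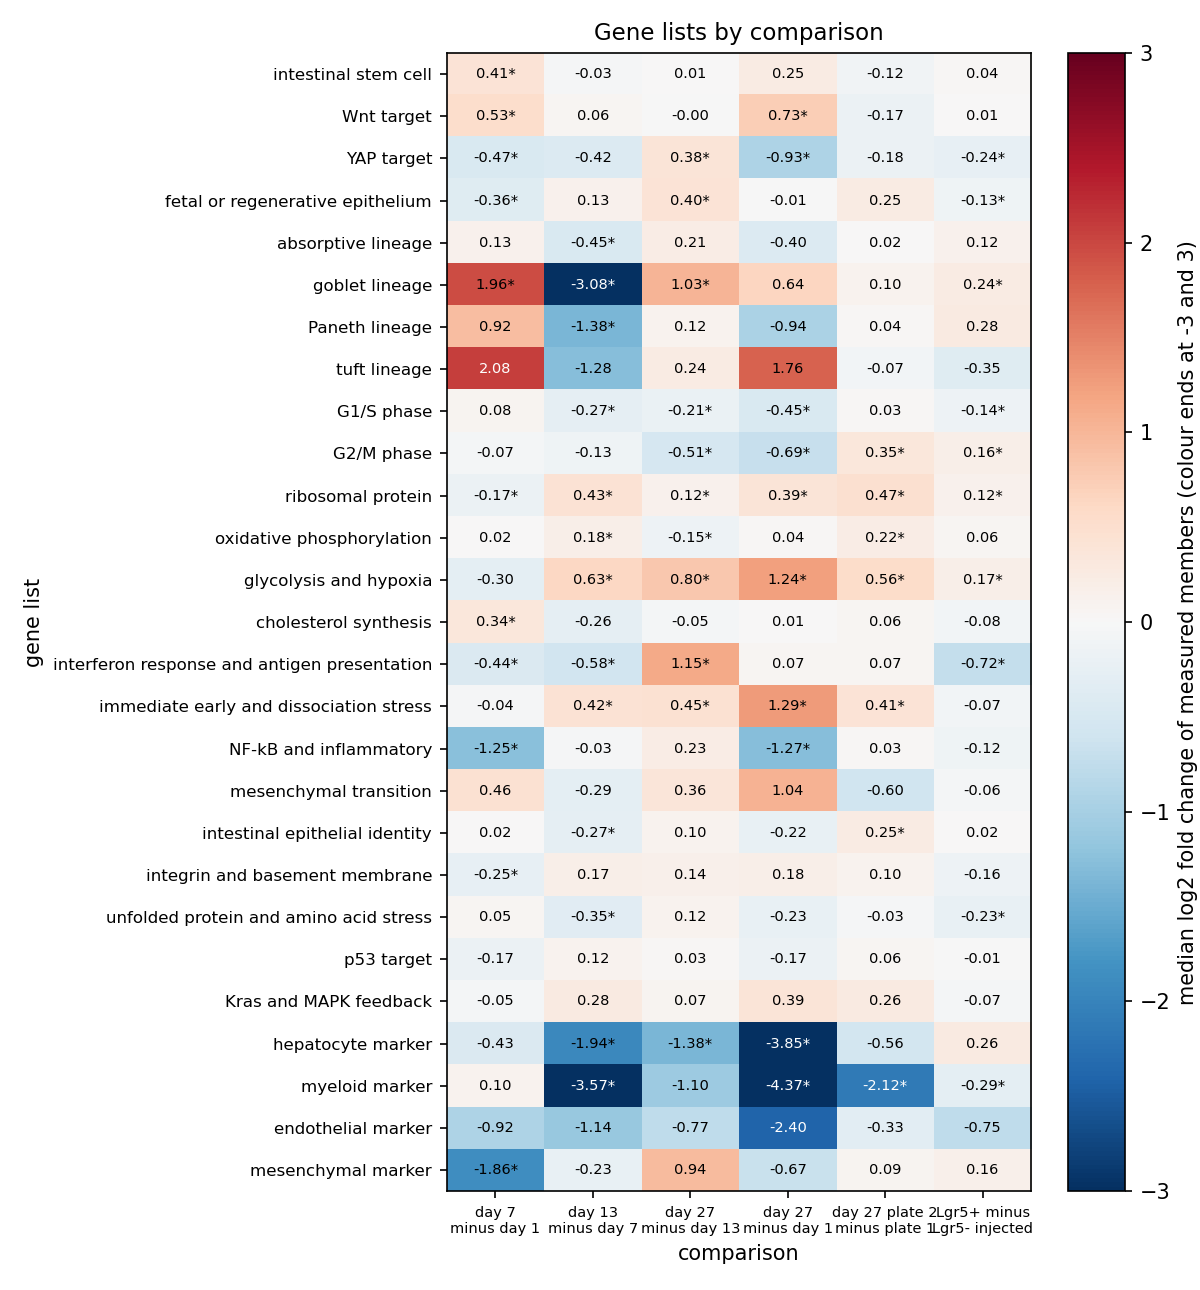
Colours show the median log2 fold change of the measured members of 27 gene lists (rows) in 6 comparisons (columns), on a scale that ends at −3 and 3, and stars mark a camera adjusted p under 0.05 with the preset correlation. Goblet genes stood at 1.96 from day 1 to day 7 and at −3.08 from day 7 to day 13, and glycolysis and hypoxia genes at 1.24 from day 1 to day 27.

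A trend over log2 day, tested against the scatter of the 5 plates, was called for 225 of 11265 genes, 144 rising and 81 falling. This balance turned under other fits, with 97 rising and 624 falling by limma on mean log values and 204 rising and 256 falling by limma-voom on half-plates. H19 rose by 1.83 per doubling of the day (edgeR adjusted p = 0.000236), and Clca4 changed by −0.87 (edgeR adjusted p = 0.000236). Alox12, a lipoxygenase, rose by 1.08 (edgeR adjusted p = 0.000803) and the claudin Cldn2 by 0.52 (edgeR adjusted p = 0.000901). The retinol receptor Stra6 (3.63), Mfsd4 (0.97) and Ptgr1 (0.42) also rose, while Arf2 (−0.43) fell. Stra6 was at 0 CPM in all half-plates of days 1 and 7, so its slope depends on the prior count. The trend counted 20 genes without the first day 27 plate, 90 without the second and 136 without day 1, and 23 with other cell types kept. Of these 20, 76, 43 and 20, in that order, were among the 225. Most of the 225 were thus lost without the single day 1 plate, and likewise without either day 27 plate. H19, Clca4, Mfsd4 and Arf2 were not called with the day untransformed, Arf2 was not called without day 1, nor was Cldn2 with other cell types kept.

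Few genes separated the cells recovered from the injected Lgr5-negative and Lgr5-positive fractions. Of 10367 genes 1 was called, the YAP target Amotl2 (chromosome 9, 102716672 to 102733418), which was chosen after its values were seen because its mean of 43.6 CPM is under the limit for naming. It was lower in the Lgr5-positive half-plate on 5 of 5 plates, with 152 against 71.3 CPM at day 1 and 33.6 against 24.5 CPM on the second day 27 plate (log2 fold −0.88 ± 0.15 SE, edgeR adjusted p = 0.0250). An unadjusted p under 0.05 was reached by 863 genes, and DESeq2 called 0. Lgr5 itself was higher in the Lgr5-positive half-plate on 5 of 5 plates without passing (0.34 ± 0.11 SE, edgeR adjusted p = 0.322), and its difference by plate was 0.90 at day 1, 0.25 at day 7, 0.37 at day 13, and 0.19 and 0.10 at day 27. The DTR-eGFP reporter went the same way (0.91 ± 0.24 SE, edgeR adjusted p = 0.425), with log2 differences of 1.62 at day 1, 1.32 at day 7, 0.75 at day 13, and 0.91 and 0.13 at day 27. Amotl2 was also not called by DESeq2, after thinning to equal depth, by limma on mean log values, without a plate block, or without the plate of day 1, of day 13 or the first of day 27. The fraction effect counted 72 genes without the day 7 plate.

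Among the lists, that of unfolded protein and amino acid stress was lower in the Lgr5-positive fraction with a median of −0.23 (camera adjusted p = 5.47e-06, but an adjusted p = 0.508 with an estimated correlation). Of its 19 genes 8 were lower adjusted over the list alone and none over all genes. The interferon list was lower with a median of −0.72 (camera adjusted p = 7.52e-06, but an adjusted p = 0.608 with an estimated correlation) and 6 of 18 lower adjusted over the list alone. Its members Irf7 and Cxcl10 turned with time, with log2 differences of 0.48 and 2.24 at day 1, against −1.86 and −2.40 for Irf7 and −1.70 and −2.60 for Cxcl10 at day 27. YAP targets were lower with a median of −0.24 (camera adjusted p = 0.0126, but an adjusted p = 0.608 with an estimated correlation), 1 of 18 over all genes and 4 adjusted over the list alone. Stem cell genes (median 0.04, camera adjusted p = 0.511) and Wnt targets (0.01, camera adjusted p = 0.738) passed no test between the fractions. Wells of other cell types made up 34.1% of the Lgr5-negative and 48.0% of the Lgr5-positive half-plate at day 1, and 28.5% and 45.1% at day 7.

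Whether the difference between the fractions changed with time was tested as an interaction with log2 day, which called 31 genes, 17 with a rising and 14 with a falling difference. The heat shock genes Hspa1b and Hspb1 went from lower in the Lgr5-positive half-plate at day 1 to higher at day 27. For Hspa1b the log2 difference was −1.17 at day 1, 0.12 at day 7, 0.51 at day 13, and 0.89 and 1.22 at day 27 (slope 0.47 per doubling of the day, edgeR adjusted p = 8.87e-07). The interferon-induced genes Ifi27l2a and Ifi27l2b went the other way, with 1.23 at day 1 and −0.54 and −0.71 at day 27 for Ifi27l2b (slope −0.41, edgeR adjusted p = 7.53e-05). The slope did not pass for Lgr5 (−0.15, edgeR adjusted p = 0.596) or DTR-eGFP (−0.24, edgeR adjusted p = 0.147). Without the day 1 plate 42 genes were called, 5 of them shared, and Hspa1b and Hspb1 were not called. The count was 9 without the day 13 plate, 19 without the first and 111 without the second day 27 plate.

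The share of tumour cells with an Lgr5 transcript lay between 8.12% and 12.4% on every plate. Thinned to 1000 transcripts per cell, it was 8.13% at day 1 (13 of 160 cells, 95% interval 4.40% to 13.5%), 9.95% at day 7 (6.10% to 15.1%), 11.7% at day 13 (7.79% to 16.7%), and 12.4% (8.66% to 16.9%) and 8.12% (5.16% to 12.0%) at day 27. In myeloid-like wells, which should lack Lgr5, it was 2.61% (4 of 153, 0.717% to 6.56%). These wells had a median of 2992 transcripts at day 1 and 3501 at day 7 before thinning. Unthinned, 50.6%, 49.2%, 55.2%, 53.9% and 55.7% of tumour cells held Lgr5. The share with Clu was 15.0%, 19.9%, 56.8%, 74.2% and 73.8% over the 5 plates against 6.54% in myeloid-like wells, and that with Ly6a 48.1%, 26.7%, 15.3%, 19.1% and 26.9% against 15.7%. The share with Muc2 was 2.50%, 18.8%, 2.25%, 6.74% and 4.43%, while in myeloid-like wells it was 1.35% at day 1 and 12.7% at day 7. Mki67 was found in 16.2%, 14.7%, 15.3%, 9.36% and 12.2% of cells, against 5.88% in myeloid-like wells. Olfm4 was found in 0 of 160 cells at day 1 after thinning, which allows a share of up to 1.88% (3 counts) for cells with a transcript at this depth and sets no limit on cells that express the gene. Between the fractions the Lgr5 share differed by a mean of −0.56 percentage points over 5 plates (SD 3.95, exact sign-flip p = 0.812, adjusted p = 0.963 over 11 genes), higher in the Lgr5-positive half-plate on 1 of 5 plates. The sign depended on depth, with 3.81 points (4 of 5 plates higher, exact p = 0.188) after thinning to 2000 transcripts and 3.23 points (3 of 5 plates) unthinned. At 1000 transcripts no gene of the 11 reached an exact p under 0.312. At 2000 transcripts the DTR-eGFP share was higher in the Lgr5-positive half-plate on 5 of 5 plates (by 12.0 points) and the Ly6a share lower on 5 of 5 (−7.71 points), both with the smallest exact p that 5 plates allow and an adjusted p of 0.344.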

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

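The tests of other splits of the half-plates were set before their results were seen, and the genes named here were taken from the top of the interaction table after it was seen. The interaction of injected fraction with log2 day, a test of the difference between days itself, called 31 genes, for which chance is not excluded. The slope of the difference between Lgr5-positive and Lgr5-negative half-plates per doubling of the day was 0.47 for Hspa1b, 0.43 for Hspb1 and 0.94 for Cryab, which are heat shock genes. It was −0.41 for Ifi27l2b and −0.91 for Ifi27l2a, which interferon induces, −0.60 for the carboxylesterase Ces2a, 0.55 for A130077B15Rik and −2.43 for the chemokine Cxcl2, whose mean of 3.78 CPM is low.

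Splits of the 10 half-plates into 5 and 5 gave as many genes in 27 of 96 cases, the real split included in this and the counts that follow, which is why chance is not excluded for the 31 genes. The highest count of another split was 119. Among the 16 splits that part the half-plates of every plate, 7 gave as many and the highest other was 88. For the effect of the injected fraction, 62 of 100 splits gave at least the 1 gene called, with a highest other of 52 genes, so chance is not excluded there either. Counts several times the real one point to a structure of the samples, whose nature was not tested.

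By plate, Cryab differed between the half-plates by −3.17 at day 1, 1.75 at day 7, 0.53 at day 13, and 0.64 and 1.11 at day 27, on the log2 scale. A cluster of tumour cells led by Cryab, with Maoa and Tmem158 among its top genes, held 45 Lgr5-negative and 14 Lgr5-positive cells at day 1. Cryab at days 7 and 13 was at most 2.57 CPM, near the floor of 3 counts. Ces2a differed by 2.58, 1.62, 0.64, −0.25 and 0.36 in the same order. A130077B15Rik was among the top genes of the shallow Kcnq1ot1 cluster, which held 3 Lgr5-negative and 0 Lgr5-positive cells at day 1. DESeq2 called 10 genes for the interaction and did not call Cryab, Hspb1 or Cxcl2. Ifi27l2a and Cxcl2 were not called with other cell types kept. Limma on mean log values did not call Hspa1b, A130077B15Rik, Ces2a or Cxcl2. Without the day 1 plate Hspa1b, A130077B15Rik and Hspb1 were not called, and the cause was not tested.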

How the results depend on the processing

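Of the settings here, whole molecule numbers, Rn45s left out, the 0.3% limit on other-type markers, leaving out the Kcnq1ot1 cluster and keeping the class II cluster whole were chosen after the data were seen. Over these and the settings planned, named genes kept their side of the threshold in 6978 cases, lost the call in 440 and gained one in 65. Direction was compared only for genes called in the main setting, and it reversed in 0 cases. A gene or list with no call in either setting counted as kept. List results kept their side of the threshold in 660 cases, lost the call in 113, gained one in 24 and reversed in 1. Counts stayed within 1.5 times in 101 cases and moved in 56. With an estimated correlation 62 list calls were lost, which was all of them, and with fry 37. Size factors of DESeq2, a limit of 2000 transcripts, whole molecules and Rn45s left out moved none of the counts below. The untransformed day gave 160 trend genes, of which only 79 were shared with the 225. Where no cause is named, the cause was not tested.

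Without a gene filter the counts were 101 between the day 27 plates (main 49), 86 for the fraction effect (main 1), 74 for the interaction (main 31) and 573 for the trend (main 225), and more genes were tested. DESeq2 gave 148, 152 and 80 for the day 7, 13 and 27 steps (main 261, 261 and 156; 123, 133 and 71 shared), 2 between the day 27 plates, 0 for the fraction, 10 for the interaction and 412 for the trend. With other cell types kept the steps gave 150, 766 and 99, day 27 against day 1 1414 (main 822), the day 27 plates 26, the fraction 48, the interaction 14 and the trend 23. The added genes then include those of the liver cells, and the higher share was 13.8% against 25.7% at the day 13 step and 30.8% against 55.8% for day 27 against day 1. In that setting the myeloid marker list reversed for the fraction, to 0.91 from −0.29. The fraction effect called 6 genes at 500 transcripts or more, 2 without a mitochondrial limit and 2 with the day 27 plates summed, 3 under the 0.3% limit, 4 without the Kcnq1ot1 cluster, 4 with the class II cluster whole, 0 without a plate block and 0 after thinning. The interaction called 19 under the 0.3% limit, 18 with the class II cluster whole and 57 with plates summed. Thinning gave 95 for the day 27 step and 28 for the day 27 plates.

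Limma on mean log values gave 8, 9 and 3 for the steps, 25 for day 27 against day 1, 1 for the plates, 0 for the fraction and 721 for the trend. At an adjusted p alone the 4 contrasts had 377, 542, 81 and 2379 genes in that setting, so the day 27 step was small without the fold limit too (main 351). The higher share of trend genes was then 13.5%, and 44.3% with limma-voom, which called 460, against 64.0%. For the interaction it was 29.0% against 54.8%. At an adjusted p alone the contrasts gave 562, 523, 351 and 1955, and 42.4% of the day 13 step was higher. Leaving out each plate gave 236 to 273 for day 7, at most 315 for day 13, 67 to 229 for day 27 against day 13, 752 to 818 for day 27 against day 1, 40 to 74 for the day 27 plates, 0 to 72 for the fraction, 9 to 111 for the interaction and 20 to 329 for the trend. The day 27 step had 67 without the second day 27 plate (86.6% higher against 75.6%), and the plate pair 74 without day 1. The fraction effect had 6 without day 1, 72 without day 7, 0 without day 13 and 5 without the second day 27 plate. The interaction had 9 without day 13, 19 without the first and 111 without the second day 27 plate. The trend had 136 without day 1 (43 shared with the main 225), 20 without the first (20 shared) and 90 without the second day 27 plate (76 shared). A plate pair left with 1 plate assumes that plate to vary like the others.

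The share of cells with Lgr5 depends on depth by construction. Unthinned it was 50.6%, 49.2%, 55.2%, 53.9% and 55.7%, and thinned to 2000 transcripts it was 15.6% at day 1, 13.8% at day 7, 20.6% at day 13, and 23.9% and 16.8% at day 27. No paired analysis was possible because the groups share only replicate number 1, and the plate is already the block between fractions.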

Other observations

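The tests of a plate effect on Muc2, of a few wells as its whole cause, of plate differences for the hypoxia genes and of liver RNA among genes that are not liver markers were chosen after the result was seen. Etv4, a transcription factor downstream of Kras, rose by 1.85 from day 7 to day 13 and 1.72 from day 1 to day 27, and the phosphatase Dusp6 rose by 1.07 from day 13 to day 27 and 1.70 over the whole course. They were 2 of the 15 measured Kras and MAPK feedback genes to rise from day 1 to day 27, over all genes and adjusted over the list alone (median 0.39, camera adjusted p = 0.0582, so the list did not pass). Of 20 immediate early and dissociation stress genes 4 rose over the whole course, Hspa1a (4.76), Nr4a1 (2.75), Socs3 (1.56) and Junb (1.26), and 9 adjusted over the list alone (median 1.29, camera adjusted p = 0.000134, but an adjusted p = 0.344 with an estimated correlation). That list also differed between the day 27 plates by a median of 0.41 (camera adjusted p = 0.00437, but an adjusted p = 0.737 with an estimated correlation). From day 7 to day 13 and from day 13 to day 27 its medians were 0.42 and 0.45 with no gene called (camera adjusted p of 0.00276 and 0.000320, with adjusted p = 0.437 and 0.509 with an estimated correlation), and at day 7 Jund was lower by −1.10. The matrix protease Mmp14 rose by 2.43 and Sparc changed by −3.16 from day 1 to day 27 (liver RNA in tumour wells accounted for 157% of its fall), among 5 mesenchymal transition genes, with a further gene higher adjusted over the list alone (camera adjusted p = 0.750). Of 19 unfolded protein and amino acid stress genes Ddit3 (−1.88) and Trib3 (−2.65) fell to day 7, and Psat1 (−1.06) and Chac1 (−1.47) were lower at day 27 than at day 1, 2 and 3 adjusted over the list alone. At day 7 that list's median was 0.05 while its mean was −0.18 and its test pointed down (camera adjusted p = 0.960), at day 13 it was lower (−0.35, camera adjusted p = 0.00727, but an adjusted p = 0.356 with an estimated correlation), and for day 27 against day 1 the camera adjusted p was 0.0519.

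Replication genes of the G1/S phase were lower as a group at each step after day 7 with none of 20 called, by medians of −0.27 to day 13, −0.21 to day 27 and −0.45 over the whole course (camera adjusted p of 0.000385, 0.00173 and 6.12e-05, with adjusted p = 0.436, 0.509 and 0.344 with an estimated correlation). None of 22 ribosomal protein genes was called. Their medians were −0.17, 0.43 and 0.12 over the 3 steps (camera adjusted p of 0.00657, 2.85e-09 and 0.0273, with adjusted p = 0.832, 0.436 and 0.729 with an estimated correlation), but 0.47 between the day 27 plates alone (camera adjusted p = 3.22e-13, and an adjusted p = 0.516 with an estimated correlation). Oxidative phosphorylation genes stood at 0.18 to day 13 and −0.15 to day 27 with none of 23 called (camera adjusted p of 0.0134 and 0.0106, with adjusted p = 0.478 and 0.509 with an estimated correlation), and at 0.22 between the day 27 plates. Cholesterol synthesis genes were higher at day 7 by a median of 0.34 with none of 19 called (camera adjusted p = 0.00429, but an adjusted p = 0.187 with an estimated correlation), and Insig1 rose by 1.29 over the whole course. Of 20 epithelial identity genes only the intestinal factor Isx was called from day 13 to day 27 (1.69) and over the whole course (1.16), while the list was lower from day 7 to day 13 (−0.27, camera adjusted p = 0.00899, but an adjusted p = 0.436 with an estimated correlation). Paneth genes were lower at day 13 than at day 7 (−1.38, 1 of 6 adjusted over the list alone, camera adjusted p = 0.00276, but an adjusted p = 0.248 with an estimated correlation). In the tuft list Avil rose (3.68) and Gfi1b fell (−2.90) from day 1 to day 27 (camera adjusted p = 0.750). Among 14 p53 targets Plk2 fell to day 7 (−3.19), and over the whole course Phlda3 rose (2.49) and Trp53inp1 fell (−1.14), with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.518). Of 3 measured endothelial markers Clec4g (−4.27) and Dnase1l3 (−2.40) were lower at day 27 than at day 1 (camera adjusted p = 0.0582), and of 3 mesenchymal markers Dcn was (−5.44, camera adjusted p = 0.0989). Median and test differed in sign, with neither passing, for the interferon list (median 0.07, test down), the integrin list (0.18, test down) and the fetal list (−0.01, test up) between day 27 and day 1. They also differed from day 7 to day 13 for stem cell genes (−0.03, test up) and mesenchymal markers (−0.23, test up), from day 13 to day 27 for Paneth genes (0.12, test down), and at day 7 for oxidative phosphorylation and epithelial identity (both 0.02, test down). The NF-kB list had a median of −0.03 and a mean of 0.31 from day 7 to day 13. The enteroendocrine gene Cpe passed in no day contrast, with a highest log2 fold of 0.71 at day 13 (edgeR adjusted p = 0.0800).

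Some lists that passed between the fractions are not described elsewhere. In the Lgr5-positive half-plates the medians were 0.17 for glycolysis and hypoxia (3 higher adjusted over the list alone), 0.16 for G2/M, 0.12 for ribosomal proteins and 0.24 for goblet genes, and −0.14 for G1/S, −0.13 for fetal or regenerative (3 lower adjusted over the list alone) and −0.29 for myeloid markers. Their camera adjusted p lay between 0.00253 and 0.0185, and the adjusted p = 0.608 with an estimated correlation for each. From day 13 to day 27 goblet genes stood at a median of 1.03, 2 higher adjusted over the list alone (camera adjusted p = 0.00173), and hepatocyte markers at −1.38, 4 of 16 lower (camera adjusted p = 0.000767), both with an adjusted p = 0.509 with an estimated correlation. From day 1 to day 7 the stem cell list stood at 0.41 (camera adjusted p = 0.0136, estimated 0.194), the interferon list at −0.44 (0.0360, estimated 0.832) and mesenchymal markers at −1.86 (0.00287, estimated 0.187), and from day 7 to day 13 the interferon list stood at −0.58 (0.0498, estimated 0.659), with no member called in any. Ribosomal protein genes stood at 0.39 for day 27 against day 1 (camera adjusted p = 1.49e-05, estimated 0.481). Between the 2 day 27 plates alone the test passed for G2/M (0.35, camera adjusted p = 0.00180, estimated 0.942), epithelial identity (0.25, 0.00362, estimated 0.516), oxidative phosphorylation (3.37e-06, estimated 0.516) and myeloid markers (−2.12, 3.15e-06, estimated 0.516).

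Muc2 transcripts, which rose at day 7 and fell to day 13, sat in few cells on every plate and least so at day 7. The 10 highest tumour cells held 59.7% of them at day 7, against 95.5% at day 1, 81.7% at day 13, and 80.9% and 89.1% at day 27. Without the 10 highest cells of each plate the level was still 242.2 CPM at day 7, against 1.21 CPM at day 1 and 4.33 CPM at day 13. Tumour cells with Muc2 numbered 13, 93 and 27 at days 1, 7 and 13, so removing 10 took most of them at day 1. The day 7 remainder also exceeded the levels with all tumour cells kept, 25.1 CPM at day 1 and 21.3 CPM at day 13. This argues against a few wells as the whole cause. A plate effect stays open, since days 1, 7 and 13 have 1 plate each, although the 2 day 27 plates differed by only 0.57 on the log2 scale. Myeloid-like wells held 56.9 CPM of Muc2 at day 7 and 2.84 CPM at day 1, so free RNA on the day 7 plate may carry some of it, and a response to the liver at day 7 remains an untested hypothesis.

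Liver RNA in tumour wells could account for part of the genes lower at day 27 than at day 1. Its excess at day 1 over day 27, set by the marker genes, came to 1.28% (hepatocyte-like), 0.9495% (myeloid-like) and 1.54% (endothelial-like) of transcripts, values that may count tumour RNA as liver RNA, since Epcam was found in 91.7% of hepatocyte-like and 83.3% of endothelial-like wells. At that level it accounted for at least 50% of the fall in 25.3% of the 363 lower genes, a share that leaves its role in the whole set open. Among the 335 lower genes that are not liver markers the share was 19.1%, which argues against it as the main cause there. What lowered the others, such as Clca4 or Nfkb2, was not tested.

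The higher glycolysis and hypoxia genes at day 27 may reflect low oxygen in grown metastases, a hypothesis that was not tested. Day 27 also differed from day 1 in injected number (50000 against 400000 cells) and in sequencing run. The cells with fewer stress transcripts in each half-plate kept 98.1% of the median log2 fold (1.22 against 1.24). This argues against a response confined to the cells with the most stress transcripts. The split was made within half-plates, so stress shared by most cells of a plate during isolation stays open. The cells kept held 0.535% stress transcripts at day 1, and 0.497% and 0.580% on the day 27 plates. A difference between the day 27 plates is argued against as the whole cause. With the first day 27 plate alone the median was 1.06 and with the second 1.41, against 0.56 between those plates. The single day 1 plate entered both values, so an offset of that plate stays open. The list also rose by 0.80 from day 13 to day 27, which shared a run. It rose by 0.63 from day 7 to day 13, which shared an injected number. Neither the run nor that number changed at both steps, so neither alone accounts for both rises. The day changed together with 1 of them at each step. Days 7 and 13 had 1 plate each, and the 0.56 between the day 27 plates is close to 0.63. Plate offsets thus stay open for these steps, and the values do not single out the day.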
